A study of Homo sapiens with 6 samples.

How the data were processed

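Messenger RNA levels were measured by RNA sequencing in 6 melanoma tumours grown as patient-derived xenografts (PDX, human tumour tissue carried in mice), 3 from mice given vehicle and 3 from mice given niraparib. Groups and animal numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted from disrupted tumour tissue with a column kit. Library preparation, strandedness, read length, and the handling of reads from the mouse host are not given in the sources used here. Per the submitters' processing notes, kallisto and the genome build hg19 were named without a role, and how reads were assigned to genes is not given in the sources used here.

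The deposited gene table holds RPKM values (reads scaled to gene length and to the library total) for 16495 genes in each of the 6 libraries. The values themselves show that 1 read had been added to each count before scaling, and that libraries with 0 reads for a gene share 1 floor value. A second table by the authors gives the log2 group means, which equal the mean of log2(RPKM + 1) within 0.00051. It also holds the authors' log2 fold, with words in place of a fold for 6664 genes, and the authors' p-value and adjusted p-value per gene from a test that the headers do not name. The last column of that deposited table is a count, the highest raw read count of each gene over the 6 libraries, and no listed gene has a highest count under 5. Mitochondrially encoded genes are not among the listed genes.

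Whole reads were recovered from the RPKM values and the highest read count of each gene. With a tolerance of 0.02 reads, 100% of values came out as whole numbers, and simulated tables of 4803 genes returned 100% of their reads. The recovered totals over the listed genes were 21828988 to 35905659 reads per library. A count of 3 reads, used as the limit that 0 reads allow, equals 0.0836 to 0.137 CPM. Limits and folds derived from reads cover only the counting error of the 0 reads.

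The test fixed before the data were examined had assumed TPM. Because the tables hold RPKM, the same test was run on log2(RPKM + 1) with the filter set on RPKM. Genes with a mean of at least 1 RPKM over the 6 libraries were kept, which left 11094 genes and set aside 5401. Differences between niraparib and vehicle were tested with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every log2 fold change is niraparib minus vehicle on the log2(RPKM + 1) scale unless reads are named, and it understates the change of genes with low values. Intervals are 95% confidence intervals from the same fit.

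The 38 gene lists were fixed before the data were examined, and 29 of them had at least 5 tested members. They were tested with camera in limma, with a preset correlation between genes of 0.01 and adjustment over the lists tested. Camera with an estimated correlation and fry were run beside it. Counts of single members past the threshold are given over all genes and adjusted over the list alone. Adjustment over the list alone does not correct for the number of lists, so some single members can pass it by chance. Markers of 8 other cell types were among the lists.

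Genes were named by a rule fixed before the data were examined. It took up to 10 genes per direction past the threshold with groups that did not overlap, and, where fewer than 5 passed, the 5 with the smallest unadjusted p and groups apart. PARP1 and PARP2 were always named, as were the 4 members with the smallest p of each list past the threshold and up to 2 members of the other lists. Other genes named below were picked after their values were seen: TMSB4X beside its pseudogene, members of a list beyond the first 4, cell type markers under the filter, genes with reads in 1 group only, and members of the 2 lists added later. Y-linked genes and XIST were left out, and some genes that the rule names are not reported here.

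Alternatives planned beforehand were pseudocounts of 0.1 and 5 RPKM, no filter, a filter at 5 RPKM, median-of-ratios scaling, quantile normalization, limma without the trend, limma with array weights, each library left out, an adjusted p of 0.1, an absolute log2 fold change of at least 1, DESeq2 1.42.0 on the recovered reads, an estimated correlation, and fry. Alternatives chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood test) on the recovered reads, reads thinned to 21828988 per library, and removal of each library's trend with GC content and length by loess with a span of 0.5. GC content came from the longest GENCODE 29 transcript of each gene and was found for 97.6% of tested genes. That annotation is on another genome build than hg19, so no coordinates are given.

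The tests were tested on simulated data: reads for the listed genes drawn from the observed means and library totals, with 50 genes changed at each fold. In the simulated data 11086 genes passed the filter on RPKM for limma, while edgeR used its own filter on reads. For the niraparib comparison limma called 44% of genes changed 1.5-fold, 94% of those changed 2-fold, 96% at 3-fold and 92% at 4-fold, with 16 false calls. The edgeR test called 70%, 94%, 98% and 100% of them, with 6 false calls. A simulated list of 25 genes shifted 1.3-fold was called, and 0 of the unchanged simulated lists were. These simulated reads carried no correlation between genes, and their spread followed the trend over all genes and not each gene's own, so the rates do not carry over to genes that vary more. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.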

Results

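Tumour RNA was compared between 3 vehicle-treated and 3 niraparib-treated mice that carried a human metastatic melanoma as a xenograft. Niraparib inhibits PARP1 and PARP2, enzymes that bind DNA breaks and attach ADP-ribose chains to proteins. The labels give no dose, schedule or time of collection, and name no second tumour line. The spread between libraries is therefore a spread between mice, and the p-values do not reach beyond this tumour. Vehicle libraries 7, 21 and 24 held 21957883, 25433260 and 21828988 reads over the listed genes. Niraparib libraries 1, 3 and 12 held 30744615, 31230889 and 35905659 reads. The niraparib libraries were thus deeper by 41.4% on average, and the depths of the groups did not overlap.

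Vehicle library 7 stood apart from the other 5. On the first principal component, which held 48.2% of the variance, it lay at -25.8 and the other libraries between 3.1 and 9.1. The second component, with 22.9% of the variance, placed the vehicle libraries at -13.0 to -2.2 and the niraparib libraries at 3.3 to 11.8. Pearson correlations across genes were 0.978 to 0.992 between vehicle libraries, 0.994 to 0.995 between niraparib libraries and 0.982 to 0.994 between a vehicle and a niraparib library. Each vehicle library correlated more closely with the niraparib libraries than with the other vehicle libraries, at means of 0.9825 against 0.9791 for vehicle 7, 0.9923 against 0.9853 for vehicle 21 and 0.9905 against 0.9861 for vehicle 24.

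**Figure D1:**
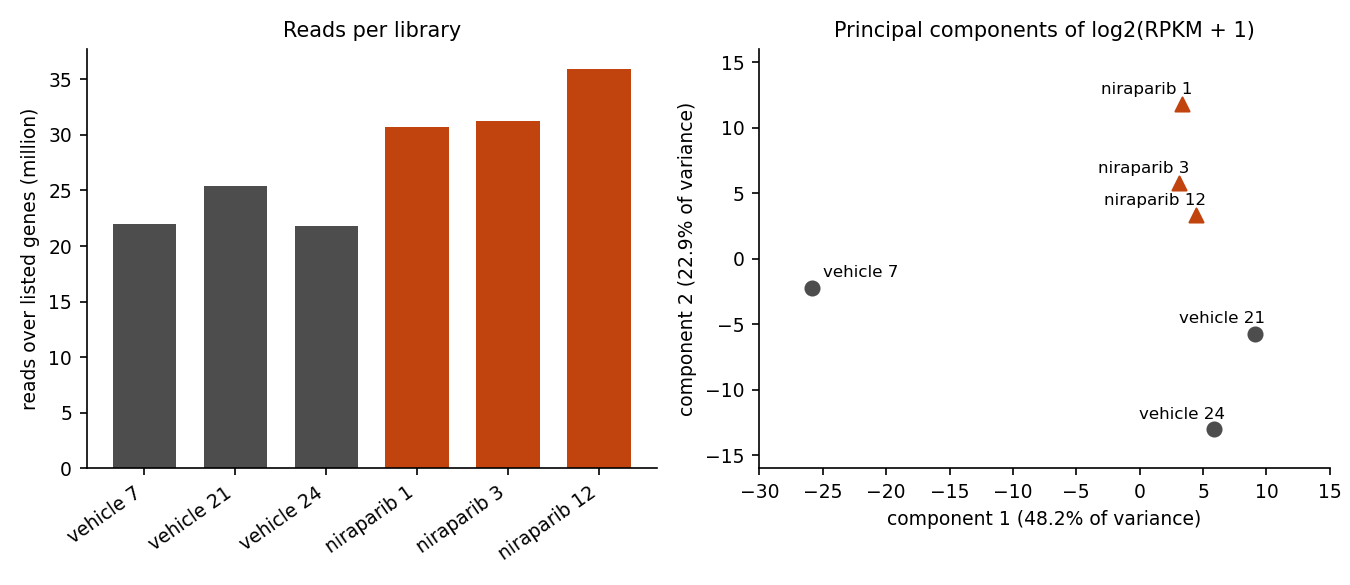
Left, recovered reads per library over the listed genes (y axis, labelled with its scale); right, the 6 libraries on the first 2 principal components of log2(RPKM + 1), with vehicle as grey circles and niraparib as orange triangles. Each niraparib library holds at least 30744615 reads and each vehicle library at most 25433260, and vehicle library 7 lies at -25.8 on component 1.

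The question of the comparison was which genes differ in expression when the melanoma is exposed to niraparib. As a list, genes of cholesterol biosynthesis rose: 22 of 23 measured members were higher, with a median log2 fold change of 0.31 (adjusted p = 0.19 with an estimated correlation, which ends the call). Fibroblast markers and extracellular matrix genes fell, with all 7 and 23 of 25 measured members lower and medians of -1.37 and -0.28 (adjusted p = 0.19 for both with an estimated correlation, which ends these calls). Mitotic genes fell by a small amount, with 35 of 35 members lower and a median of -0.20, and this call too is lost with an estimated correlation (adjusted p = 0.19). PARP1 and PARP2 showed no difference that passed the test. Single genes mostly did not pass either: limma called 2 of 11094 genes, both pseudogenes.

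In all, 13 of the 29 lists tested passed the camera threshold, 4 of them higher and 9 lower. None of the 13 passed with an estimated correlation, where the smallest adjusted p = 0.19, and none passed in fry, where the smallest adjusted p was 0.128. At an unadjusted p under 0.05 stood 630 of 11094 tested genes, 290 higher and 340 lower, where chance gives a share of 0.05. That count was 1655 without vehicle library 7, 1132 without vehicle library 21 and 584 without vehicle library 24. It was 296, 334 and 403 without niraparib library 1, 3 or 12, and 2644 with array weights. The 3 niraparib values lay all above the 3 vehicle values for 637 genes and all below for 750, together 12.5% of tested genes, where chance gives 10%. The authors' deposited table lists 0 genes at an adjusted p under 0.05, a smallest adjusted p of 0.196, and 1099 of 16495 genes at an unadjusted p under 0.05. On the recovered reads edgeR called 0 genes, with 955 of 14319 at an unadjusted p under 0.05, and DESeq2 called 114, of which 37 were higher and 77 lower. With array weights limma called 478 genes, 201 higher and 277 lower. Vehicle libraries 7, 21 and 24 had weights of 0.114, 0.582 and 2.541, so on the vehicle side these calls rest mostly on library 24. Leaving vehicle library 7 out gave 0 genes.

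**Figure D2:**
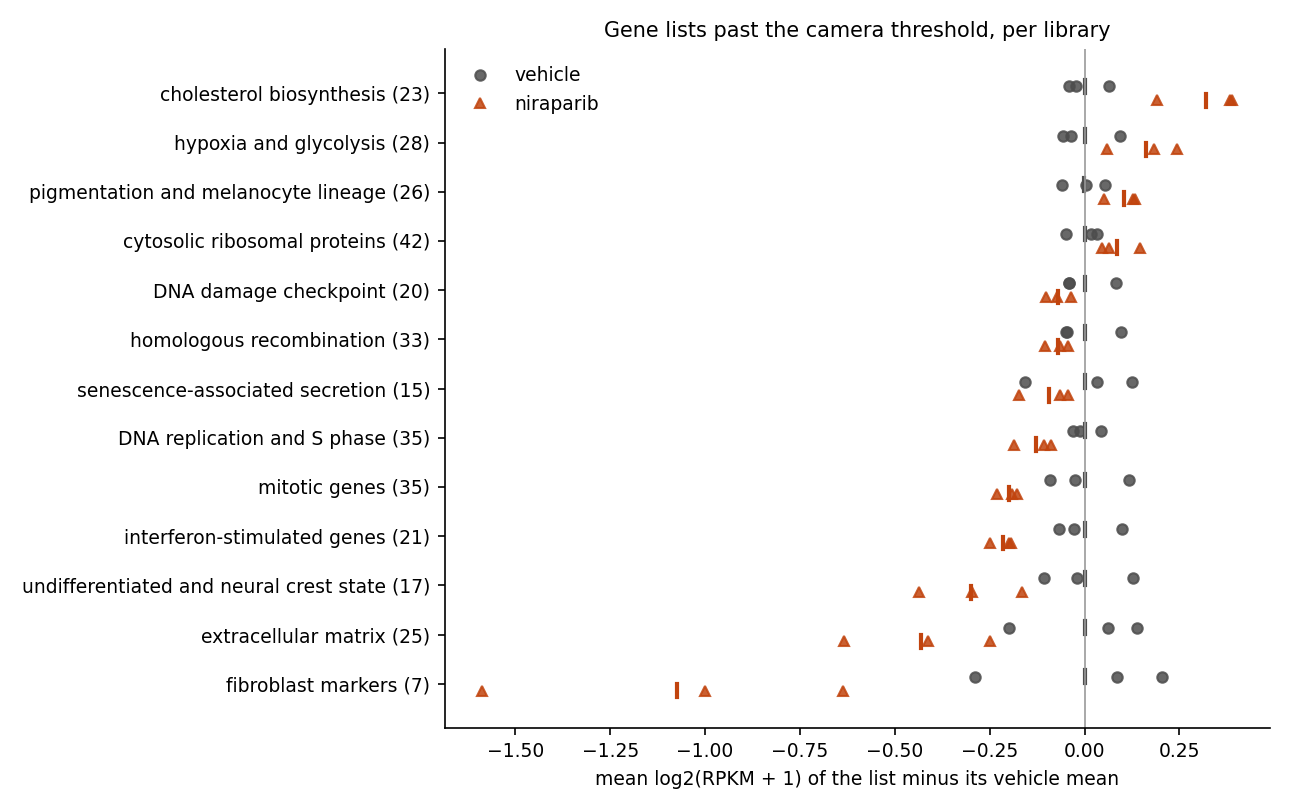
Mean log2(RPKM + 1) of each gene list past the camera threshold, per library, as the difference from the mean of the 3 vehicle libraries (x axis, log2 units); grey circles are vehicle, orange triangles niraparib, vertical ticks the group means, and the number of tested members stands in brackets. Fibroblast markers lie at -1.59, -1.0 and -0.64 in the niraparib libraries and at -0.29, 0.09 and 0.20 in the vehicle libraries, while the cholesterol list lies at 0.38, 0.39 and 0.19 in the niraparib libraries. The groups overlap for hypoxia and glycolysis, pigmentation, senescence-associated secretion, homologous recombination and DNA damage checkpoint genes.

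The targets of niraparib had nearly the same level in both groups. PARP1 was at 57.0 ± 3.43 RPKM (SD, n = 3) in vehicle and 56.3 ± 0.553 RPKM (SD, n = 3) in niraparib tumours, a log2 fold change of -0.02 with an interval of -0.20 to 0.16. PARP2 was at 20.2 ± 1.61 RPKM (SD, n = 3) and 19.97 ± 0.638 RPKM (SD, n = 3), with an interval of -0.21 to 0.18. Among the 18 measured members of the PARP family 10 were higher and 8 lower, and 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.54). PARP16 and PARP9 had the smallest p in the family, with log2 fold changes of 0.19 and -0.16. Over the alternatives they ran from 0.083 to 0.293 and from -0.234 to -0.048. Of 15 genes of NAD synthesis and consumption, which supply or use the substrate of PARP enzymes, 8 were higher and 7 lower (adjusted p = 0.885), and mean and test lay below 0 while the median was 0.03. QPRT, an enzyme of NAD synthesis from tryptophan, had 0.52 and narrowly passed adjusted over the list alone (limma adjusted p = 0.0493, and 0.454 over all genes). BST1, which hydrolyses NAD, had -0.28.

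Cholesterol genes gave the largest list difference upwards. The list exceeded other genes by 0.32 on the log2 scale (camera adjusted p = 1.55e-18, and adjusted p = 0.19 with an estimated correlation). No member passed over all genes, and 12 of 23 passed adjusted over the list alone, all higher. DHCR7, the last enzyme of the Kandutsch-Russell branch of cholesterol synthesis, was at 9.64 ± 0.353 RPKM (SD, n = 3) in vehicle and 14.5 ± 1.68 RPKM (SD, n = 3) in niraparib, a log2 fold change of 0.54 (SE 0.10). TM7SF2 and MVD, enzymes of the same pathway, each had 0.39. SREBF2, which encodes the transcription factor that drives these genes, had 0.47, and HMGCS1, an early enzyme of the pathway, had 0.55. Among these 12, the groups overlapped for INSIG1 alone.

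**Figure D3:**
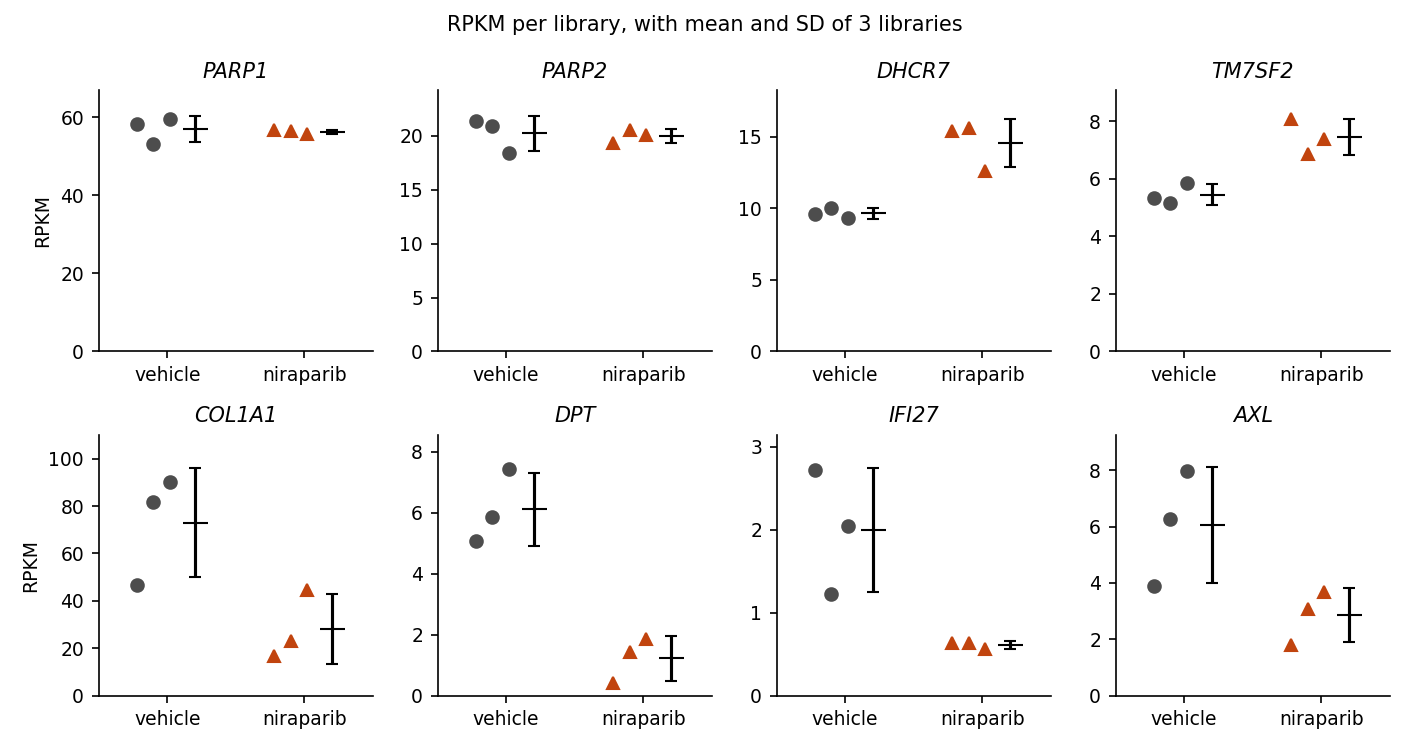
RPKM (y axis, linear and from 0) of 8 genes in each library, vehicle as grey circles and niraparib as orange triangles, with the mean and SD of 3 libraries as bars beside the points. PARP1 and PARP2 overlap between the groups, DHCR7 and TM7SF2 lie higher in each niraparib library, and COL1A1, DPT, IFI27 and AXL lie lower; none of the 8 passed over all genes.

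Of the 29 lists, fibroblast markers differed most from other genes, with a difference of -1.07 on the log2 scale (camera adjusted p = 1.42e-11, and adjusted p = 0.19 with an estimated correlation). All 7 measured markers passed adjusted over the list alone, and 0 passed over all genes. DPT, which encodes the matrix protein dermatopontin, was at 6.11 ± 1.21 RPKM (SD, n = 3) in vehicle and 1.23 ± 0.738 RPKM (SD, n = 3) in niraparib, a log2 fold change of -1.72 (SE 0.24). The fibrillar collagen genes COL3A1, COL1A1 and COL1A2 had -1.43, -1.41 and -1.37. ACTA2, a marker of contractile fibroblasts and smooth muscle, had -0.90. DCN and LUM, which fibroblasts usually express at high levels, were at 0.298 and 0.363 RPKM in vehicle and 0.344 RPKM each in niraparib, while COL1A1 was at 72.9 RPKM in vehicle. Reads of host mouse cells that align to human genes would be counted in such values, and the sources used here do not say how they were handled.

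Extracellular matrix genes differed from other genes by -0.43 on the log2 scale (camera adjusted p = 2.53e-12, and adjusted p = 0.19 with an estimated correlation). The list shares COL1A1, COL1A2, COL3A1 and POSTN with the tested fibroblast markers, and it put the 6 libraries in the same order as they did. Of its 25 members 7 passed adjusted over the list alone, all lower. Besides the 3 collagen genes above these included SPARC, a collagen-binding matrix protein, at -0.53, and BGN, a matrix proteoglycan, at -0.91. TNC had -0.57 and COL5A2 -0.45.

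Proliferation genes were lower by small amounts in nearly every member. The mitotic list had a camera adjusted p = 4.35e-16, and adjusted p = 0.19 with an estimated correlation, with the groups apart for 23 of 35 members. No member passed over all genes or adjusted over the list alone. ASPM and ANLN, which act at the spindle and in cytokinesis, had -0.36 and -0.28, UBE2C, a partner of the anaphase-promoting complex, had -0.26, and the mitotic kinase CDK1 had -0.30. Of 35 genes of DNA replication and S phase 34 were lower, with a median of -0.12 (camera adjusted p = 8.54e-07, and adjusted p = 0.232 with an estimated correlation). Mitotic genes and genes of DNA replication and S phase were both highest in vehicle library 7, at 0.117 and 0.043 above the vehicle mean, and without it their differences from other genes were -0.135 and -0.099 in place of -0.199 and -0.127. Among replication genes CCNE2 and CCNE1, the E-type cyclins, had -0.36 and -0.23, RRM2, a subunit of ribonucleotide reductase, -0.30, and POLA1, the catalytic subunit of DNA polymerase alpha, -0.23. Of the replication-dependent histone genes 4 were measured, too few for a test, and HIST1H2BK passed adjusted over the list alone at -0.32 while HIST1H2AC had -0.20.

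DNA repair genes moved little. Homologous recombination genes were lower in 26 of 33 cases with a median of -0.06 (camera adjusted p = 0.0165, and adjusted p = 0.456 with an estimated correlation), and EXO1, RPA3 and GEN1 had -0.27, -0.24 and -0.23. DNA damage checkpoint genes were lower in 15 of 20 cases with a median of -0.08 (camera adjusted p = 0.0485, and adjusted p = 0.448 with an estimated correlation), with CHEK1, CDC25C, ETAA1 and RNF8 at -0.22, -0.20, -0.18 and -0.12. Both lists were at their highest in vehicle library 7, at 0.10 and 0.08 above the vehicle mean. Without that library their differences from other genes were -0.01 and -0.02, with an adjusted p = 0.665 for each. The homologous recombination call was also lost without niraparib library 1 (adjusted p = 0.084), and the checkpoint call without vehicle library 21 (adjusted p = 0.0566) or niraparib library 1 (adjusted p = 0.146) or 3 (adjusted p = 0.0587). Both calls were also lost with a filter at 5 RPKM, where the differences were -0.062 and -0.06 (adjusted p = 0.105 and 0.155). With array weights they were lost at -0.013 and -0.018 (adjusted p = 0.671 for each). With the GC and length trend removed they were lost at -0.047 and -0.054 (adjusted p = 0.0543 and 0.0922). Fanconi anaemia genes (13 of 20 lower, adjusted p = 0.131), non-homologous end joining genes (11 of 14 lower, adjusted p = 0.648) and genes of base excision and single-strand break repair (14 of 24 higher, adjusted p = 0.885) did not pass. In these 3 lists UBE2T and C19orf40 had -0.31 and -0.23, POLL and POLM both 0.22, and NEIL3 and NEIL2 -0.23 and -0.20. POLM was 0.087 without vehicle library 7. The 26 measured p53 target genes did not pass (adjusted p = 0.648): their median was -0.02 and their mean 0.01, with the test downwards, and RPS27L and TRIAP1 had -0.23 and -0.25. GDF15 had the largest change among the p53 targets, at 0.86 (SE 0.47).

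Interferon-stimulated genes fell as a list, with 17 of 21 members lower and a median of -0.17 (camera adjusted p = 5.39e-06, and adjusted p = 0.19 with an estimated correlation). The score of interferon-stimulated genes was highest in vehicle library 7, 0.098 above the vehicle mean, and the difference from other genes was -0.213 with that library and -0.159 without it (adjusted p = 0.00469). Adjusted over the list alone 5 members passed, all lower. IFI27 went from 2.0 ± 0.751 RPKM (SD, n = 3) to 0.609 ± 0.0444 RPKM (SD, n = 3), and IFI6, USP18, BST2 and IRF9 had log2 fold changes of -0.62, -0.43, -0.66 and -0.31. STAT2, the partner of IRF9 in interferon signalling, had 0.25 in the other direction. Genes of MHC class I antigen presentation did not pass (17 of 21 lower, adjusted p = 0.0788), although B2M, the invariant light chain, passed adjusted over the list alone at -0.34, and ERAP1 had -0.11. That list passed without vehicle library 7 (adjusted p = 0.000562) or niraparib library 3 (adjusted p = 0.0241), with array weights (adjusted p = 0.0305) and with the GC and length trend removed (adjusted p = 0.0119). MHC class II genes were higher in 5 of 7 cases (adjusted p = 0.0862), with HLA-DQB1 at 0.28 and HLA-DRB1 at 0.20, values that are uncertain because near-identical HLA genes can share reads. This list passed without vehicle library 21 (adjusted p = 0.0171) or niraparib library 12 (adjusted p = 0.00543). Cytosolic DNA sensing genes (8 of 13 lower, adjusted p = 0.329) and NF-kB target genes (8 of 13 lower, adjusted p = 0.345) did not pass, although the NF-kB list passed downwards with no filter (adjusted p = 0.0352) and in edgeR (-0.212, adjusted p = 0.0222). SAMHD1 and TMEM173, which encodes STING, had -0.35 and 0.24, and ICAM1 and RELB had 0.34 and -0.25.

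Genes of the undifferentiated and neural crest state fell, with 15 of 17 members lower and a median of -0.24 (camera adjusted p = 1.22e-06, and adjusted p = 0.19 with an estimated correlation). The receptor kinase AXL had -0.86, the adhesion molecule L1CAM -0.66, THBS1 -0.64 and TNC -0.57, and these 4 passed adjusted over the list alone. TNC and THBS1 encode matrix proteins that stromal cells also make. The undifferentiated and neural crest list moved with the fibroblast markers: both were lowest in niraparib library 1, followed by niraparib 3 and 12 and vehicle 7, 21 and 24, at -0.436, -0.297, -0.165, -0.106, -0.021 and 0.127 for the first and -1.587, -1.0, -0.637, -0.289, 0.086 and 0.204 for fibroblast markers. Pigmentation and melanocyte lineage genes rose, with 20 of 26 members higher and a median of 0.11 (camera adjusted p = 0.00286, and adjusted p = 0.19 with an estimated correlation). Leaving out vehicle library 21 ended this call, with an adjusted p = 0.0556. On the score of the pigmentation list niraparib library 12 (0.051) lay below vehicle library 7 (0.054), so the groups overlapped. PMEL, a melanosome matrix protein, was at 3575 ± 237 RPKM (SD, n = 3) and 4091 ± 242 RPKM (SD, n = 3), a log2 fold change of 0.20. Under quantile normalization PMEL was at 0.00, but that setting gives a gene with the same rank in each library the same value. For a gene at so high a level the 0.00 therefore does not test the rise. APOE had 0.42, MLPH 0.40 and CDK2 0.21, and CDK2 is uncertain because it overlaps PMEL on the other strand. MITF, TYR and DCT were at -0.06, -0.05 and -0.15. MAPK pathway output genes, which read out BRAF and RAS signalling, were split 9 to 9 (adjusted p = 0.534), with ETV5 at 0.23 and ETV4 at 0.21.

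Hypoxia and glycolysis genes rose, with 24 of 28 members higher and a median of 0.13 (camera adjusted p = 1.65e-06, and adjusted p = 0.232 with an estimated correlation). The groups overlapped on the score of this list, with niraparib library 12 at 0.058 and vehicle library 24 at 0.093. The glycolytic enzyme ALDOC passed adjusted over the list alone at 0.65, and NDRG1, PDK1 and ADM had 0.67, 0.40 and 0.36. Cytosolic ribosomal protein genes rose, with 40 of 42 members higher and a median of 0.08 (camera adjusted p = 8.95e-07, and adjusted p = 0.284 with an estimated correlation). The cytosolic ribosomal proteins list differed from other genes by 0.086, and by 0.055 without vehicle library 24 or without niraparib library 1. RPL8, RPL7A, RPLP1 and RPL12 had 0.20, 0.19, 0.17 and 0.16, which are uncertain because ribosomal protein pseudogenes can share reads. Senescence-associated secretion genes fell, with 10 of 15 lower and a median of -0.12 (camera adjusted p = 0.0166, and adjusted p = 0.19 with an estimated correlation), and IGFBP7 at -0.35 was the 1 member that passed adjusted over the list alone. IGFBP5 and IGFBP3 had -0.51 and -0.23, and IGFBP5 was -0.24 without niraparib library 1. GDF15, with the largest change of the list, went the other way at 0.86 (SE 0.47). The senescence list differed from other genes by -0.094, and by -0.175 without vehicle library 7, whose score of -0.156 lay below those of niraparib libraries 3 and 12 (-0.044 and -0.066). The call was lost without vehicle library 21 (-0.079, adjusted p = 0.143), without vehicle library 24 (-0.038, adjusted p = 0.0593) and without niraparib library 1 (-0.055, adjusted p = 0.0683). With a filter at 5 RPKM it was lost too, although the difference did not shrink there (-0.128, adjusted p = 0.115).

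The other lists did not pass in the main test. Genes of the unfolded protein and integrated stress response were higher in 14 of 24 cases (adjusted p = 0.142), with HERPUD1 at 0.25 and PHGDH at 0.27. Heat shock and immediate early genes were lower in 12 of 17 cases (adjusted p = 0.25), with FOS at -0.43 and NR4A1 at -0.16. FOS was -0.085 without vehicle library 7, and NR4A1 -0.075 without vehicle library 24. The heat shock list passed downwards with no filter (adjusted p = 0.0352) and in edgeR (-0.235, adjusted p = 0.0132). Apoptosis regulators were lower in 12 of 20 cases (adjusted p = 0.648), with BIRC7 at 0.35 and CASP9 at 0.19. Nuclear-encoded oxidative phosphorylation genes were lower in 26 of 34 cases (adjusted p = 0.193), and passed downwards with array weights (adjusted p = 0.0464). NDUFB3 had -0.19 and NDUFV2 -0.18, and without vehicle library 7 they had -0.074 and -0.061. Drug efflux transporters were higher in 7 of 12 cases (adjusted p = 0.648), with a mean of -0.01, a median of 0.05 and the test upwards. ABCA1, a cholesterol exporter, passed adjusted over that list alone at -0.82, and ABCC1 had 0.18. Other cell types had too few markers above the filter for a test: 2 for endothelial cells (EGFL7 at 0.08, ENG at -0.03), 1 for macrophages and myeloid cells (CD68 at -0.08), 2 for keratinocytes (DSP at 0.32, KRT10 at -0.09), 1 for adipocytes (LPL at -0.23), and 0 for lymphocytes, skeletal muscle and red blood cells.

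Among single genes, the 2 that passed were processed pseudogenes with few reads. AC144568.4 (ENSG00000253620) held 2, 2 and 3 reads in the vehicle libraries and 31, 21 and 22 in the niraparib libraries, with a log2 fold change of 1.71 (limma adjusted p = 0.0402). KB-1125A3.10 (ENSG00000228039) held 2, 2 and 1 reads against 30, 19 and 25, with a log2 fold change of 1.19 (limma adjusted p = 0.0424). Both are uncertain, since reads of a parent gene can be counted on a pseudogene, and edgeR gave them an adjusted p of 0.114 and 0.0959.

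The genes next in order did not pass. On the higher side they included FADS2, a fatty acid desaturase, at 0.75, ALDOC at 0.65, the long noncoding RNA AC074389.5 at 0.63 and the antisense RNA RP11-283G6.3 at 0.86. The last is uncertain because strand-specific counting is not stated. On the lower side DPT had -1.72, the chemokine CXCL14 -1.37 (adjusted p = 0.0782), NCKAP1L, a blood cell subunit of an actin regulatory complex, -0.70, and the actin-capping gene CAPG -0.68. TMSB4XP8, a pseudogene of the actin-binding peptide gene TMSB4X, was at 178 ± 25.2 RPKM (SD, n = 3) in vehicle and 78.6 ± 12.6 RPKM (SD, n = 3) in niraparib, a log2 fold change of -1.17 (adjusted p = 0.0782). TMSB4X itself had -0.10, so the pseudogene's value is uncertain where the 2 share reads. Reads of host mouse cells would be counted in it too where they align, which the sources used here do not settle.

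The limma test used 3 libraries per group and called 94% of simulated 2-fold changes and 44% of 1.5-fold ones, but of the 14 measured genes with an absolute log2 fold change of at least 1 it called 2, so the simulated rates do not show which changes were detectable in these tumours. With a library left out, AC144568.4 passed only without niraparib library 1 or 12, and KB-1125A3.10 did not pass or fell under the filter each time.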

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

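Genes under the filter of the main test were searched for reads in 1 group only, and the search was chosen after the data were seen. It found 6 genes with 0 reads in each library of a group and at least 5 reads in each library of the other. RP11-507K2.3, an antisense RNA, had 66 reads over the niraparib libraries and 0 over the vehicle libraries, which makes it at least 15.6-fold higher against a floor of 3 reads over the group. RP11-77P6.2, also antisense, had 80 reads against 0, at least 18.9-fold higher. AC093838.5, a pseudogene, had 69 against 0, at least 16.3-fold higher. MYH8, a muscle myosin heavy chain, had 58 against 0, at least 13.7-fold higher. RP11-6N17.9, a noncoding transcript, had 31 against 0, at least 7.31-fold higher. PTPN5, a neuronal tyrosine phosphatase, had 41 reads over the vehicle libraries and 0 over the niraparib libraries, at least 19.3-fold lower. The folds are scaled to the depth of the groups and take the reads of the higher group as exact, so each limit covers only the counting error of the 0 reads. A gene is also found more easily when the deeper niraparib libraries hold its reads, as for all but PTPN5. Antisense genes and pseudogenes can take reads from a partner gene. None of the 6 passed in edgeR, where 4 were tested with an adjusted p of 0.0867 to 0.121. The 6 libraries can be divided into 3 and 3 in 10 ways, so no share of splits under 0.1 can be reached. The real split gave 6 such genes and the highest of the others gave 5, and 1 of the 10 splits gave as many.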

How the results depend on the processing

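All counts here refer to the limma test and the camera lists unless another tool is named, and edgeR, thinning and the GC and length correction were chosen after seeing the data. The count of 2 genes became 0 with a pseudocount of 5, with no filter, with a filter at 5 RPKM, with median-of-ratios scaling, with edgeR on recovered reads and with thinned reads. It became 1 with quantile normalization and with the GC and length trend removed, 4 at an adjusted p under 0.1, 478 (201 higher) with array weights and 114 (37 higher) with DESeq2; the smallest adjusted p ranged from 4.54e-11 to 0.123. The count of 630 of 11094 tested genes at an unadjusted p under 0.05 became 1070 of 16495 with no filter and 364 of 6977 with a filter at 5 RPKM. It became 2644 of 11094 with array weights, 1170 of 10831 with the GC and length trend removed and 955 of 14319 in edgeR. With a library left out it was 296 to 1655. The settings tested different numbers of genes, which accounts for part of these differences in count. Leaving out a library gave 0 to 2 genes: 0 without vehicle 7, 21 or 24 or niraparib 3, 1 without niraparib 1 and 2 without niraparib 12. The count of 13 lists became 0 with an estimated correlation and 0 in fry, 17 in edgeR, 16 with no filter, 9 with a filter at 5 RPKM, 12 with the GC and length trend removed, and 10 to 14 with a library left out. Of the 13 lists, 9 kept their call and direction in each alternative with the preset correlation that gave a value (with a filter at 5 RPKM, fibroblast markers had under 5 members). Pigmentation, senescence secretion, homologous recombination and DNA damage checkpoint genes lost it in 1, 4, 5 and 7 of 17, the last 2 also with the GC and length trend removed. Of the lists not called, MHC class I passed in 4, MHC class II in 2 of 16, NF-kB targets in 2, heat shock and immediate early genes in 2 and oxidative phosphorylation in 1. Of 101 named genes 95 kept their sign, 49 passed with array weights and 23 with DESeq2. Apart from PARP1 and PARP2 they were chosen by p-value in these same libraries, so the counts do not carry over to other genes.

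Reversed values were small, and none had an adjusted p under 0.19; the cause was not tested. PARP2 was 0.006 with quantile normalization, 0.087 with array weights, 0.013 with the GC and length correction, and -0.079 to 0.024 with a library left out, above 0 without vehicle 7, vehicle 21 or niraparib 1. PARP1 was 0.016 with quantile normalization and -0.066 to 0.016 with a library left out (above 0 without vehicle 24). PMEL was 0.000 with quantile normalization, which gives a gene with the same rank in each library the same value. EGFL7 was -0.262 with array weights. With a library left out EGFL7 was -0.173 (without vehicle 7) to 0.324, ENG -0.18 to 0.116 (above 0 without vehicle 21 or niraparib 1), and KRT10 -0.223 to 0.011 (without niraparib 12). NAD genes were 0.009 with a pseudocount of 5, 0.070 with a filter at 5 RPKM, and -0.035 to 0.015 with a library left out (above 0 without vehicle 21, vehicle 24 or niraparib 1). The p53 targets were -0.001 with a pseudocount of 5, -0.016 with a filter at 5 RPKM, -0.028 with array weights and -0.016 (without vehicle 7) to 0.033 with a library left out. End joining genes were 0.007 with that filter, 0.014 with array weights and -0.024 to 0.007 (without vehicle 7) with a library left out. Efflux transporters were 0.068 with that filter, and -0.037 to 0.026 with a library left out (above 0 without vehicle 24 or niraparib 1). MAPK output was -0.048 with array weights and -0.046 (without vehicle 7) to 0.071 with a library left out, and apoptosis regulators -0.048 to 0.006 (without vehicle 24). Base excision genes were 0.000 in edgeR, -0.002 with the GC and length correction, and -0.004 to 0.019 with a library left out (below 0 without vehicle 7, vehicle 24 or niraparib 12).

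Across genes, log2 fold change correlated with GC content at 0.286 and with length at -0.05; genes are not independent replicates. The values of the authors' second table could not replace the first, since it gives group means but no value per library. No paired analysis was possible because the groups share no animal numbers. The 2 pseudogenes called rest on at most 31 reads in a library, and neither passed with thinned reads.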

Other observations

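The edgeR folds on recovered reads, the 2 added gene lists, the test of other cell types and the tests of depth and of GC content were chosen after the main result was seen, and the tests of depth, GC content and the added lists were set out before their own values were known. With genes under the filter included, edgeR log2 folds on the recovered reads cover further markers of other cell types, of which none passed in edgeR. Of 12 fibroblast markers with enough reads 11 were lower, with a median of -1.03, including PDGFRA at -1.71 and FBLN1 at -0.82. TEK and KDR, receptors of endothelial cells, had -2.08 and -1.12, while VWF, ENG and EGFL7 had -0.26, -0.04 and 0.05. CSF1R, a macrophage receptor, had -1.90, with mean levels of 1.51 RPKM in vehicle and 0.403 RPKM in niraparib, while CD68 had -0.09 and LYZ 1.08. PTPRC and IL7R of lymphocytes had -1.60 and -0.91. Adipocyte markers were lower in 3 of 3 cases, with a median of -0.38: PLIN1 had -2.52, LPL -0.38 and CFD -0.13. Keratinocyte markers were higher in 3 of 4 cases, with a median of 0.27, and pigmentation genes in 22 of 29 cases, with a median of 0.13.

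Fibroblast and extracellular matrix genes were lower in the niraparib tumours. With reads thinned to the smallest total the fibroblast list still lay at -1.08 against other genes, and with the GC and length trend removed at -1.07. It was past the threshold in both with the preset correlation, but with an estimated correlation the fibroblast list did not pass (adjusted p = 0.19). The second value argues against GC content and length as the whole cause. Thinning keeps each gene's expected share of the reads, so it evens out the number of reads only. Anything else that differed with depth cannot be told apart from niraparib, since the depths of the groups did not overlap. Fewer reads from all cells other than melanoma cells might account for the lower fibroblast list. Over endothelial, myeloid and lymphocyte markers the medians on recovered reads were -0.261, -0.093 and -1.26, with standard errors of 0.507, 1.09 and 0.43. These errors come from the spread between the few markers of each list and do not measure the spread between mice. With 5, 3 and 2 markers measured, a loss of all such cells and a loss of fibroblast transcripts alone cannot be told apart. Whether the reads came from melanoma cells or from human or mouse stroma was not tested, since the tables hold no sequence. An effect of niraparib on any of these cells stays open.

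Cholesterol genes were higher, at 0.32 against other genes. Thinning left the list at 0.319 and the GC and length correction at 0.321, past the threshold in both with the preset correlation. With an estimated correlation the cholesterol list did not pass (adjusted p = 0.19). The corrected value argues against GC content and length as the whole cause, while thinning evens out the number of reads only. An effect of niraparib on sterol synthesis is a hypothesis that these libraries leave open, as is a difference between the mice that the labels do not record. A candidate explanation, a shared rise of SREBP targets, was tested on 17 fatty acid synthesis genes without SCD and FADS2, already seen to be higher. These lay at 0.116 above other genes (camera adjusted p = 0.00534 over the 2 added lists, adjusted p = 0.195 with an estimated correlation), with FASN at 0.50 and ACSS2 at 0.37 passing adjusted over the list alone, but 7 of 17 were lower.

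Mitotic genes were lower in 35 of 35 cases. The list lay at -0.20 after thinning and at -0.168 after the GC and length correction, past the threshold in both with the preset correlation. With an estimated correlation the mitotic list did not pass (adjusted p = 0.19). The corrected value argues against GC content and length as the whole cause, while thinning evens out the number of reads only. The difference was -0.135 to -0.245 with a library left out or another setting. A lower share of dividing cells may underlie it, which no value here tests, and vehicle library 7 had the highest score of the list, 0.12 above the vehicle mean.

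ABCA1, which LXR receptors induce when sterols are high, was lower at -0.82. If LXR targets fell together, 10 others without ABCA1 and APOE should be lower. They lay at -0.078 against other genes, with 6 of 10 lower and an adjusted p of 0.136, so the test left this open. NR1H3, which encodes an LXR receptor, had -0.31 and ABCG1 -0.34, while 4 of the 10 were higher, among them SCARB1 at 0.14. APOE, set aside because its value had been seen, went the other way from ABCA1, at 0.42.

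Other splits of the libraries can test chance only coarsely, since 10 splits exist and the smallest share is 0.1. For genes the real split gave 2 and the highest other split 1, and for lists 13 against 12, so 1 of 10 splits gave as many in each case. The split that gave 12 lists set vehicle libraries 7 and 24 with niraparib library 12 against the rest. For single lists the difference in the real split was 0.322 for cholesterol genes against at most 0.248 in the others, 1.07 against 0.832 for fibroblast markers, 0.199 against 0.139 for mitotic genes, 0.213 against 0.133 for interferon-stimulated genes. For these lists past the threshold another split gave a larger difference: 0.163 against 0.182 for hypoxia and glycolysis, 0.094 against 0.163 for senescence-associated secretion, 0.105 against 0.119 for pigmentation and melanocyte lineage, 0.07 against 0.075 for homologous recombination and 0.069 against 0.077 for DNA damage checkpoint genes. Mitotic genes were called in 6 of the 9 other splits and cholesterol genes in 3. Each of these splits still sets 2 libraries of a group against 2 of the other, so a real difference is partly kept in it, and the calls expected from that were not computed.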
